A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

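Poly-A RNA of 12 yeast libraries was measured, 2 for each of 6 groups: WT and cho2 cells in YPL, and at 1 h and 3 h after a switch to SL at an A600 of 1.0. Per the labels' protocols, YPL was a rich medium of yeast extract (1%) and peptone (2%), and SL a minimal medium of nitrogen base (0.17%) and ammonium sulfate (0.5%) that lacked amino acids; lactate (2%) was the carbon source in both. Libraries were made from 4 µg of RNA with a stranded TruSeq kit and read on a HiSeq 2500, per the labels' protocols. The series text calls the pairs biological replicates, but nothing says that they came from separate cultures, so the p-values may measure technical spread only.

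The deposited signal values were made by the authors with Bowtie and DESeq on genome build sacCer2, per the submitters' processing notes; versions, counting tool, annotation and use of strand are not given in the sources used here. In each deposited column 100% of the values were whole multiples of 1 step within 0.01 reads, as in gene counts divided by 1 factor. In 3 columns (both WT libraries in YPL and the first cho2 library at 3 h) the step lay near 1, at 1.01, 1.01 and 0.998. Values there were still not whole numbers, such as CHO2 at 1887.7, 1570.5 and 3.9914 for 1868, 1554 and 4 recovered reads. Undivided counts would not give such values, so a step other than 1 holds there too. The reads recovered by dividing by that step ranged from 3.17 M (M for mega, second WT library at 3 h) to 12.5 M, with 9.17 M as the second lowest. Of the 6685 listed genes, 6006 matched the reference table (release R64), which was used for names, neighbours, overlap and copies, and 679 did not. Values of overlapping genes are therefore uncertain: YAL004W, antisense to SSA1, was at 0.3 to 0.393 of it.

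Differences were tested with limma 3.58.1 in R 4.3.3 (limma-trend on log2 of value + 1) for the 6546 genes at 10 or more in at least 2 libraries. All libraries entered 1 fit with 1 mean per group and 6 residual degrees of freedom, and 11 contrasts were drawn: cho2 minus WT in each medium and time, each pair of times within a strain, and the interactions at 1 h and 3 h. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Gene lists, 42 in number, were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The libraries, contrasts, tests, gene lists and the rule for naming genes were chosen before the data were examined, as were most alternatives. Replicate numbers were not used as a block.

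Genes were named by this rule. In each contrast the text could name the 6 largest rises and 6 largest falls that passed, had a mean of at least 50 in the higher group, were fully separated between replicates and had a standard symbol. It could also name up to 4 members with the smallest adjusted p of each list called by camera or close to the study's question, CHO2, and 20 genes of methionine, SAM, phospholipid and methylation biology. The neighbours of CHO2 and a set of mating-type genes were also listed in advance. Genes named otherwise are marked as chosen after their values were seen.

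Alternatives were a pseudocount of 5, no filter and a filter at 50, TMM scaling (edgeR 4.0.16), quantile normalization, a replicate block, only the groups of a contrast, edgeR and DESeq2 1.42.0 on recovered reads, and each library left out in turn. edgeR with TMM, DESeq2 with its own size factors, and leaving out both 3 h libraries numbered 2 were added after the data were seen. Near-identical copies were defined with blastn 2.17.0 as genes with at least 95% identity over at least 50% of their length, and 274 of 6006 had one. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

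The procedure was tested on simulated data with 200 changed genes. At a fold of 2, limma found 83.6% of them for the strains in YPL, 88.1% at 1 h, 92.5% at 3 h and 35.8% and 43.3% for the interactions, and at a fold of 1.5 it found 28.4%, 22.4%, 16.4%, 3% and 13.4%. False calls made up 4.7%, 2.8%, 5.4%, 3.2% and 8.9% of its calls. The simulated counts were independent, with 1 level and 1 spread per gene in all groups apart from the set changes. They were scaled by the same factors that made them. The deposited libraries may differ in spread between groups, in scaling and in shared deviations, so these rates may be too favourable for them. On the deposited data edgeR with the deposited scaling called 27 genes in YPL, 653 at 1 h and 219 at 3 h. Reads and alignments were not used here.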

Results

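RNA from budding yeast was sequenced in 12 libraries, 2 for each of 6 groups. A wild-type (WT) strain was compared with a strain lacking CHO2 (called cho2), the gene for the methyltransferase that starts the conversion of phosphatidylethanolamine to phosphatidylcholine with S-adenosylmethionine (SAM) as methyl donor. Both strains were sampled during growth in YPL, a rich medium with lactate as carbon source, and 1 h and 3 h after a switch to SL, a minimal lactate medium with ammonium sulfate and no amino acids. The title of the series poses the question of what phospholipid and histone methylation do for metabolism. Values are normalised read counts given as mean ± SD (n = 2), and differences are log2 ratios ± SE.

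The table listed 6685 genes, of which 6546 were tested. WT libraries 1 and 2 held 9.48 M and 9.53 M recovered reads (M for mega) in YPL, 9.17 M and 11.1 M at 1 h in SL, and 9.28 M and 3.17 M at 3 h. The cho2 libraries 1 and 2 held 10.1 M and 11.3 M in YPL, 10.03 M and 12.5 M at 1 h, and 9.52 M and 11.9 M at 3 h. The replicates of a group correlated across genes with r from 0.976 to 0.996, where genes are not independent replicates. On the first principal component, with 65.4% of the variance, the 4 YPL libraries lay between 53.1 and 61.4 and the 8 SL libraries between -32.0 and -26.4. In the second cho2 library at 3 h the median gene lay at -0.33 log2 from the mean of the 12 libraries, against -0.06 to 0.17 in the others.

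CHO2 (YGR157W) was close to absent in every cho2 library. Its level was 1729 ± 224 in WT in YPL, 3597 ± 662 at 1 h and 2258 ± 349 at 3 h, against 5.26 ± 2.11, 6.98 ± 3.13 and 5.06 ± 1.51 in cho2. The cho2 libraries held 4 to 12 reads of the gene, and the highest cho2 value was 0.585% of the lowest WT value. In WT, CHO2 itself rose by 1.05 ± 0.29 at 1 h in SL (limma adjusted p = 0.0032; both SL libraries above both YPL libraries). The neighbouring gene PTI1 was read at 298 and 380 in WT in YPL and at 342 and 364 in cho2, and MTR3 at 613 and 563 in WT and 393 and 391 in cho2 (limma adjusted p = 0.24, log2 -0.58, lower in 2 of 2 cho2 libraries).

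**Figure D1:**
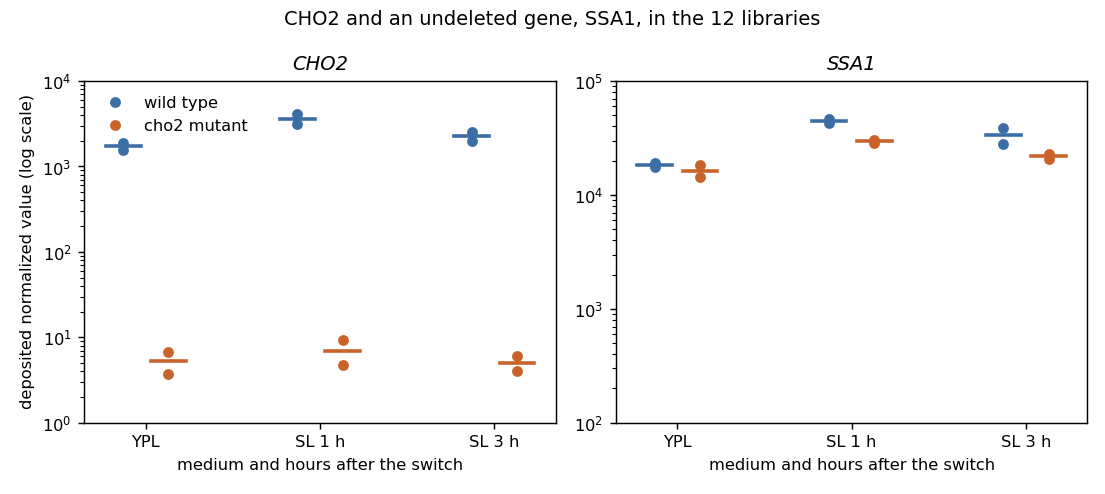
Normalised read counts (log axis) of CHO2 and of SSA1, a chaperone gene left intact in both strains and chosen after its values were seen, in YPL and at 1 h and 3 h in SL; points are libraries and bars are means of 2. CHO2 lay between 1571 and 4065 in the WT libraries and between 3.77 and 9.19 in the cho2 libraries.

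In YPL, where the comparison asks what loss of CHO2 changes during rich growth, 6 of 15 sulfate and methionine genes were higher in cho2 (list adjusted p = 0.313 with an estimated correlation). MET3, for ATP sulfurylase, stood at 2487 ± 460.4 in cho2 against 356 ± 31.5 in WT (log2 2.79 ± 0.18, limma adjusted p = 2.9e-10; 2 of 2 cho2 libraries above both WT libraries). MET17, for homocysteine synthase, was higher by 2.20 ± 0.19, although its reading frame overlaps YLR302C and strand use in counting was not given. The kinase gene MET14 was higher by 1.77 ± 0.19, MET16 for the reductase of the activated sulfate by 1.38 ± 0.21, and the sulfite reductase subunit genes MET10 and MET5 by 1.63 ± 0.17 and 1.53 ± 0.18. MHT1, whose enzyme makes methionine from S-methylmethionine, was higher by 1.63 ± 0.19. The acid phosphatase genes PHO11 and PHO12, near-identical copies that cannot be read apart, stood lower in cho2 (PHO12 -1.31 ± 0.19).

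Of the lists, sulfate and methionine synthesis had 6 of 15 genes higher and 0 lower (8 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.9e-24 with the preset correlation, adjusted p = 0.313 with an estimated correlation). Of the 42 lists, camera with the preset correlation called 8 lists up and 8 down, and with an estimated correlation 0 lists, those named below included, with adjusted p = 0.313 as the lowest. The list of sulfur amino acid uptake and salvage, which holds the permease genes MMP1 and MUP1, had 3 of 12 higher (6 higher and 1 lower adjusted over the list alone). The genes for peroxisomal beta-oxidation of fatty acids had a median of 0.53 with 0 of 15 passing limma over all genes, 13 higher adjusted over the list alone, and 13 at an unadjusted p under 0.05, 0 in edgeR and 7 in DESeq2. Cytosolic ribosomal protein genes had a median of -0.41 with 0 of 137 passing limma and 0 adjusted over the list alone, 63 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2.

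Genes of 4 other lists near the question did not pass in YPL. Among the 22 genes of phospholipid synthesis other than CHO2, 0 passed limma, with 2 at an unadjusted p under 0.05, 1 in edgeR and 0 in DESeq2 (0 higher and 1 lower adjusted over the list alone). Of the 14 genes for histone methylation and demethylation 0 passed, with 0 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2. Of the 14 PP2A-family phosphatase genes 0 passed, with 0 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2, and the last 2 lists also had 0 adjusted over the list alone. The SAM cycle had 0 of 7, with 3 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2 (1 higher and 2 lower adjusted over the list alone).

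In all, limma called 27 of the 6546 genes between the strains in YPL, 22 higher in cho2 and 5 lower, and 456 genes had an unadjusted p under 0.05. Without the second cho2 YPL library the count fell to 11 genes.

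At 1 h in SL, where the comparison asks how the mutant meets a medium without amino acids, 14 of 15 sulfate and methionine genes were lower in cho2 (list adjusted p = 0.187 with an estimated correlation). MUP1, the high-affinity methionine permease gene, was lower at -3.12 ± 0.18, and JLP1, for a sulfonate dioxygenase, and YCT1, for a cysteine transporter, at -2.86 ± 0.24 and -2.50 ± 0.22 on the log2 scale. SAM1, for SAM synthetase, was lower at -2.29 ± 0.18, its paralog SAM2 at -1.26 ± 0.18, CYS3 for cystathionine gamma-lyase at -2.11 ± 0.17 and CYS4 for cystathionine beta-synthase at -1.38 ± 0.20. CYS4 lies near the deleted CHO2 on the chromosome, next after PTI1. SHM2, which encodes the cytosolic serine hydroxymethyltransferase that feeds one-carbon units into methionine and purine synthesis, stood at 736 ± 27.4 in cho2 against 8730.4 ± 802 in WT (log2 -3.56 ± 0.17, limma adjusted p = 4.2e-13; both cho2 libraries below both WT libraries). The glycine decarboxylase genes GCV1 and GCV2 were lower, at -2.16 ± 0.18 and -1.86 ± 0.17, and ADE17 of purine synthesis at -1.99 ± 0.20.

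INO1, for inositol-phosphate synthase and a classical target of repression by phospholipid precursors, was higher in cho2, at 6221 ± 166 against 1263 ± 37.3 (log2 2.30 ± 0.16, limma adjusted p = 3.6e-10; both cho2 libraries above). The formate dehydrogenase gene FDH1 was higher at 3.10 ± 0.19, and FDH2, which overlaps YPL276W, at 3.01 ± 0.19. By 3 h FDH1 no longer stood higher in cho2, at 10257 and 7789 in its libraries against 14440 and 11052 in WT. Of 11 genes of lactate use and gluconeogenesis 7 were higher and 1 lower (8 and 2 adjusted over the list alone; list adjusted p = 0.187 with an estimated correlation). ADY2 for an acetate transporter was higher at 2.06 ± 0.20, FBP1 for the gluconeogenic bisphosphatase at 1.68 ± 0.17 and JEN1 for the lactate permease at 1.09 ± 0.17, and DLD3 was lower at -0.96 ± 0.18.

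By list, 14 of 15 sulfate and methionine genes were lower and 0 higher (15 lower adjusted over the list alone), with a median of -1.16 (camera adjusted p = 7.8e-20 with the preset correlation, adjusted p = 0.187 with an estimated correlation). With the preset correlation, camera called 6 lists up and 8 down, and with an estimated correlation 0 lists, those named below included, with adjusted p = 0.175 as the lowest. Uptake and salvage had 11 of 12 lower (11 lower and 1 higher adjusted over the list alone). Purine and one-carbon synthesis had 16 of 22 lower (16 adjusted over the list alone), and transsulfuration and glutathione 6 of 14 (7 adjusted over the list alone). The SAM cycle had 4 of 7 (6 adjusted over the list alone) and the iron regulon 8 of 24 (12 lower and 1 higher adjusted over the list alone). Higher in cho2 were 56 of 137 cytosolic ribosomal protein genes (77 adjusted over the list alone; median 0.51), such as RPL34A at 1.13 ± 0.21. Relative to the median of all genes, this list stood at 0.31 against the first WT library at 1 h and at 0.85 against the second. The size of the difference thus depended on the WT library. Ribosome biogenesis had 6 of 76 higher (10 adjusted over the list alone), which became 33 with TMM scaling.

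Phospholipid synthesis other than CHO2 had INO1 higher and PSD1, for a phosphatidylserine decarboxylase, lower among 22 genes (1 and 1 adjusted over the list alone), and CHO1 and OPI3 did not pass. The histone methylation list had 1 of 14 lower (1 adjusted over the list alone), SWD1 of the histone H3 lysine methyltransferase complex; the calls of SWD1 and PSD1 ended when the second WT or the second cho2 library at 1 h was left out, among others. SET1, SET2 and DOT1, the histone lysine methyltransferase genes, did not pass between the strains in YPL, at 1 h or at 3 h. PP2A-family genes had 0 of 14 pass limma, with 3 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2, and 0 adjusted over the list alone.

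Limma called 604 genes between the strains at 1 h, 238 higher in cho2 and 366 lower. With TMM scaling 1003 genes passed and the higher share moved from 39.4% to 53.1%. The count ranged from 192 genes without the first cho2 library at 1 h to 1013 without the second cho2 library at 3 h.

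**Figure D2:**
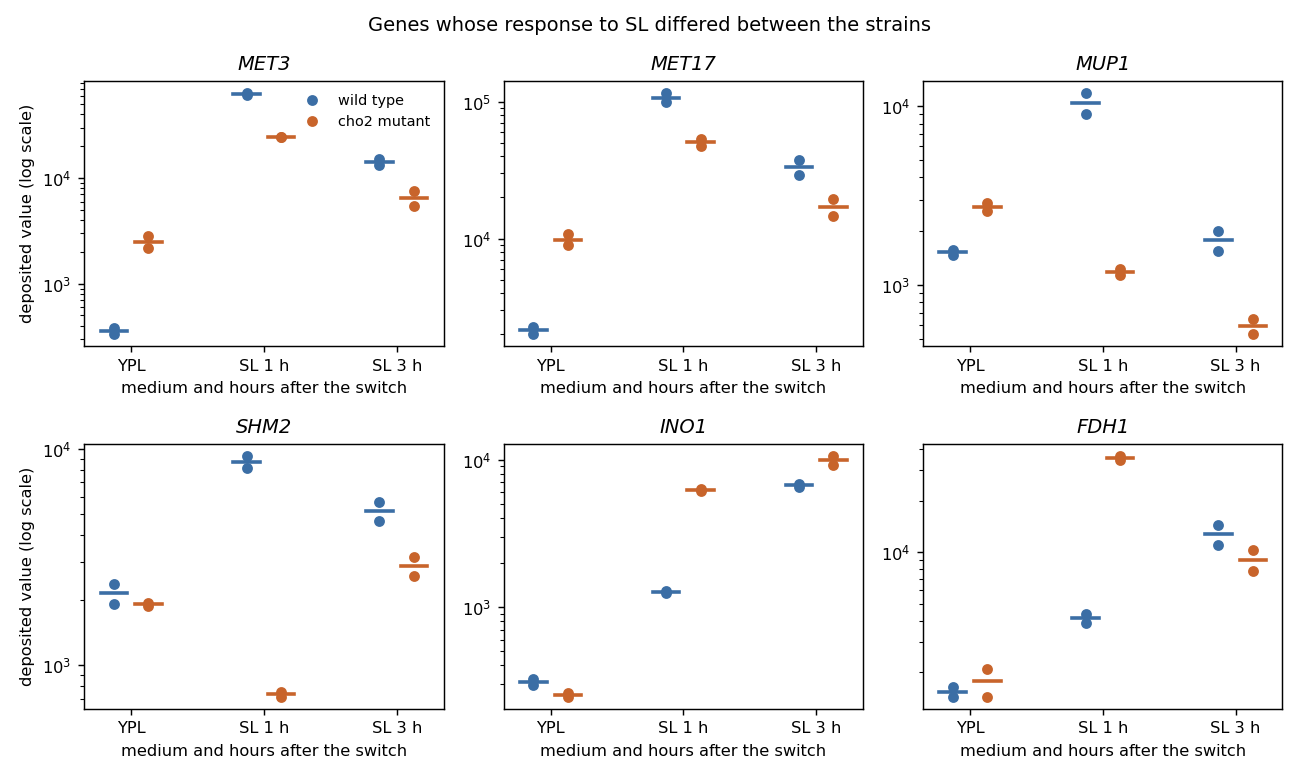
Normalised read counts (log axis) of MET3, MET17, MUP1, SHM2, INO1 and FDH1 in YPL and at 1 h and 3 h in SL, for WT and cho2; points are libraries and bars are means of 2. MET3 rose to 62757 in WT and 24456 in cho2 at 1 h, and INO1 to 1263 and 6221.

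At 3 h in SL 12 of 15 sulfate and methionine genes were lower in cho2 (list adjusted p = 0.386 with an estimated correlation). JLP1 was lower at -2.52 ± 0.24, MUP1 at -1.58 ± 0.18, CYS3 at -1.51 ± 0.17, SAM1 at -1.19 ± 0.18, MET3 at -1.15 ± 0.18 and MET6 at -1.04 ± 0.17 on the log2 scale (limma adjusted p from 4.9e-07 for JLP1 to 0.00107 for MET6; 2 of 2 cho2 libraries below both WT libraries). CHA1, the serine and threonine deaminase gene, was lower at -2.31 ± 0.24, AGP3 for a permease of sulfur amino acids at -1.93 ± 0.17, BDS1 for a sulfatase at -1.59 ± 0.19, PDC6, a pyruvate decarboxylase isoform poor in sulfur, at -1.52 ± 0.17, and the phosphate transporter gene PHO84 at -1.06 ± 0.19. Higher in cho2 were HO, the mating-type endonuclease gene, at 1.47 ± 0.24, SPS100, a spore wall gene, at 1.34 ± 0.19, and EGO4, for a small stress-related protein, at 1.29 ± 0.21.

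The sulfate and methionine list had 12 of 15 genes lower (14 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.4e-15 with the preset correlation, adjusted p = 0.386 with an estimated correlation). Camera with the preset correlation called 4 lists up and 18 down, and with an estimated correlation 0 lists, those named below included, with adjusted p = 0.386 as the lowest. Uptake and salvage had 6 of 12 lower (7 adjusted over the list alone). The SAM cycle had 5 of 7 (6 adjusted over the list alone), purine and one-carbon synthesis 8 of 22 (16 adjusted over the list alone), and daughter cell separation, with DSE4 for a septum-degrading glucanase, 4 of 11 (8 adjusted over the list alone). The histone genes HTB2 and HHF2 were 2 of 10 higher in cho2 (3 higher and 1 lower adjusted over the list alone). Histone methylation genes had 0 of 14 pass limma, with 1 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2, and PP2A-family genes 0 of 14, with 3 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2 (0 and 2 adjusted over the list alone). INO1 was higher at 0.56 ± 0.16 (limma adjusted p = 0.0488; 2 of 2 libraries above). That call ended in edgeR, with the 4 libraries of the comparison alone, and without any single library other than the cho2 libraries at 3 h.

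Limma called 225 genes at 3 h, 40 higher in cho2 and 185 lower. With TMM scaling 121 were higher and 232 lower, and the higher share moved from 17.8% to 34.3%. With the 4 libraries of the comparison alone 38 genes passed, and DSE4, HTB2 and HHF2 were not among them. The count was 130 without the first WT library at 3 h and 1116 without the first cho2 library at 3 h.

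In WT, the switch to SL asks which genes respond to the change from the rich to the minimal medium. Nitrogen base and ammonium sulfate replaced yeast extract and peptone, and no unswitched culture was sampled at 1 h or 3 h. Loss of amino acids therefore cannot be told apart from other changes of the medium, time or handling. At 1 h MET3 rose from 356 ± 31.5 to 62757 ± 1488 (log2 7.46 ± 0.18, limma adjusted p = 7.3e-20; both SL libraries above both YPL libraries). MET6 rose by 6.69 ± 0.17, MET16 by 6.65 ± 0.21, STR3 for cystathionine beta-lyase by 6.09 ± 0.18, SAM2 by 3.45 ± 0.18 and MUP1 by 2.76 ± 0.18. HOM3, which commits aspartate to threonine and methionine, rose by 3.72 ± 0.17, and the stress genes CTT1 for catalase and GRE1 by 5.76 ± 0.17 and 5.41 ± 0.19. Genes that fell included PTR2 for a peptide transporter (-7.64 ± 0.29), DIP5 for an amino acid permease (-5.21 ± 0.18) and ARO10 of amino acid breakdown (-6.03 ± 0.18). The copper transporter genes CTR1 and CTR3 also fell (-7.08 ± 0.17 and -6.47 ± 0.18).

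Of the lists in WT at 1 h, sulfate and methionine genes rose in 14 of 15 and fell in 0 (14 and 0 adjusted over the list alone; median 4.41; camera adjusted p = 2.4e-14 with the preset correlation, adjusted p = 0.269 with an estimated correlation). Of the 42 lists, camera with the preset correlation called 14 lists up and 10 down, and with an estimated correlation 0 lists, those named below included, with adjusted p = 0.184 as the lowest. All 137 cytosolic ribosomal protein genes fell (137 adjusted over the list alone), with a median of -2.78. So did 66 of 67 mitochondrial ones (66 adjusted over the list alone), 71 of 76 ribosome biogenesis genes (71 adjusted over the list alone), and all 8 amino acid and peptide permease genes under control of the sensor of external amino acids (8 adjusted over the list alone). Autophagy genes rose in 25 of 31 (25 adjusted over the list alone). Amino acid synthesis other than sulfur rose in 31 of 55 with 9 falling (31 and 9 adjusted over the list alone), and respiratory chain genes fell in 34 of 40 with 1 rising (35 and 1 adjusted over the list alone). Phospholipid synthesis had 11 rising and 1 falling of 22 (11 and 1 adjusted over the list alone), among them INO1 at 2.03 ± 0.16 and OPI3, for the later methyltransferase of the pathway, at 1.41 ± 0.16. The demethylase genes JHD2 and RPH1 rose by 1.62 ± 0.21 and 1.62 ± 0.19, and GIS1 fell (-1.18 ± 0.18).

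Limma called 2209 genes that rose and 1557 that fell at 1 h in WT, with a median over all genes of 0.18 log2. TMM scaling moved that median by -0.16 and gave 1971 rising and 2089 falling, so the rising share moved from 58.7% to 48.5%.

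At 3 h in WT 13 of 15 sulfate and methionine genes stood above YPL and 1 below (13 and 1 adjusted over the list alone; list adjusted p = 0.341 with an estimated correlation). MET3 stood above by 5.32 ± 0.18 and MET6 by 4.79 ± 0.17, and INO1 had risen by 4.43 ± 0.16. PIR3 for a cell wall protein rose by 5.46 ± 0.18 and PMA2 for a plasma membrane proton pump by 5.18 ± 0.16. Genes that fell included CTR1 (-7.38 ± 0.17), the metal reductase gene FRE7 (-5.90 ± 0.19) and CLN1 (-2.91 ± 0.19), a cyclin gene of the start of the cell cycle. Cytosolic ribosomal protein genes fell in 134 of 137 (136 adjusted over the list alone), and the replication and cell cycle entry list fell in 13 of 20 with 1 rising (13 and 1 adjusted over the list alone). With the preset correlation, camera called 12 lists up and 7 down, and with an estimated correlation 0 lists, with adjusted p = 0.295 as the lowest. Limma called 1500 genes that rose and 2013 that fell (1894 and 2192 with TMM scaling).

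From 1 h to 3 h in WT, cytosolic ribosomal protein genes rose in 130 of 137 with 1 falling (132 and 1 adjusted over the list alone), with a median of 1.15, and ribosome biogenesis genes in 71 of 76 (73 adjusted over the list alone). Camera with the preset correlation called 10 lists up and 7 down, and with an estimated correlation 0 lists, those named below included, with adjusted p = 0.356 as the lowest. All 15 sulfate and methionine genes fell (15 adjusted over the list alone), as did all 12 genes of the list for the entry into mitosis (12 adjusted over the list alone), with SWI5, a transcription factor gene, at -2.56 ± 0.20. OLE1 for the fatty acid desaturase rose by 2.82 ± 0.17 and PHO84 by 3.02 ± 0.19, while CYS3 fell (-3.35 ± 0.17). Limma called 726 genes that rose and 1671 that fell, and TMM scaling moved the median of all genes by 0.19 log2 and the rising share from 30.3% to 51.3%. The count of 2397 fell to 1355 without the second WT library at 1 h.

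In cho2, the switch to SL asks the same of the mutant. At 1 h INO1 rose from 254 ± 11.8 to 6221 ± 166 (log2 4.61 ± 0.16, limma adjusted p = 3.3e-17; 2 of 2 SL libraries above), MET6 by 4.64 ± 0.17, MET16 by 4.32 ± 0.21 and MET3 by 3.31 ± 0.18, whereas MUP1 fell (-1.20 ± 0.18). LYS1 of lysine synthesis rose by 3.30 ± 0.17 and HOM3 by 3.19 ± 0.17. PTR2 (-8.83 ± 0.29), CTR1 (-7.60 ± 0.17) and the ribosomal protein gene RPL3 (-3.84 ± 0.19) fell. Sulfate and methionine genes rose in 14 of 15 and fell in 1 (14 and 1 adjusted over the list alone), with a median of 2.46 (camera adjusted p = 8.1e-12 with the preset correlation, adjusted p = 0.375 with an estimated correlation). Cytosolic ribosomal protein genes fell in 135 of 137 (135 adjusted over the list alone; median -1.82), and proteasome genes rose in 26 of 33 (27 adjusted over the list alone). Of the 42 lists, camera with the preset correlation called 13 lists up and 10 down, and with an estimated correlation 0 lists, with adjusted p = 0.145 as the lowest. Limma called 1648 genes that rose and 1612 that fell (1785 and 1996 with TMM scaling).

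At 3 h in cho2, INO1 stood 5.28 ± 0.16 above YPL, PMA2 4.67 ± 0.16, MET6 3.19 ± 0.17 and the thiamine synthesis gene THI4 3.85 ± 0.19, and MRPL40 of the mitochondrial ribosome fell (-4.02 ± 0.18). Mitochondrial ribosomal protein genes fell in 66 of 67 (66 adjusted over the list alone) and genes of the TCA and glyoxylate cycles, such as IDH1, in 15 of 20 with 5 rising (15 and 5 adjusted over the list alone). With the preset correlation, camera called 9 lists up and 8 down, and with an estimated correlation 0 lists, with adjusted p = 0.333 as the lowest. Limma called 1296 genes that rose and 2420 that fell, and TMM scaling moved the median of all genes by 0.13 log2 and the rising share from 34.9% to 45.0%.

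From 1 h to 3 h in cho2, cytosolic ribosomal protein genes rose in 84 of 137 with 4 falling (98 and 4 adjusted over the list alone), and all 15 sulfate and methionine genes (15 adjusted over the list alone) and all 12 genes of mitotic entry (12 adjusted over the list alone) fell. Camera with the preset correlation called 6 lists up and 11 down, and with an estimated correlation 0 lists, with adjusted p = 0.55 as the lowest. SHM2 rose by 1.96 ± 0.17, GCV1 by 1.84 ± 0.18, ACC1 for acetyl-CoA carboxylase by 1.94 ± 0.19 and OLE1 by 2.68 ± 0.17, while MET3 (-1.94 ± 0.18) and the cytokinesis gene HOF1 (-3.25 ± 0.19) fell. Limma called 523 genes that rose and 1555 that fell, and TMM scaling moved the median of all genes by 0.19 log2 and the rising share from 25.2% to 50.2%. The count of 2078 fell to 1221 without the first cho2 library at 1 h.

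The responses of the strains to SL were compared by the interaction test, which asks whether a gene moved by a different amount in cho2. At 1 h MET3 rose by 3.31 in cho2 and 7.46 in WT, a difference of -4.15 ± 0.26 (limma adjusted p = 2.0e-10; each difference between an SL and a YPL library of cho2 lay below each of WT). MET17 differed by -3.29 ± 0.27, MET10 by -3.33 ± 0.24, MUP1 by -3.97 ± 0.25 and SHM2 by -3.41 ± 0.24, the last with a change of -1.38 in cho2 and 2.03 in WT. FDH1 rose more in cho2 by 2.93 ± 0.27 and INO1 by 2.58 ± 0.22. Sulfate and methionine genes had a lower response in cho2 in 13 of 15 (13 adjusted over the list alone), with a median of -1.99 (camera adjusted p = 1.1e-34 with the preset correlation, adjusted p = 0.0674 with an estimated correlation), and cytosolic ribosomal protein genes had a higher one in 54 of 137 (119 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 8.7e-72 with the preset correlation, adjusted p = 0.252 with an estimated correlation). Limma called 106 genes with a response higher in cho2 and 130 lower, and 903 had an unadjusted p under 0.05. Camera with the preset correlation called 8 lists up and 8 down, and with an estimated correlation 0 lists. The count of 236 genes fell to 97 without the second cho2 YPL library, and rose to 419 without the second cho2 library at 3 h and to 418 with TMM scaling.

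At 3 h the difference in response was -3.94 ± 0.26 for MET3, -3.18 ± 0.27 for MET17, -2.48 ± 0.27 for MET14 and -2.68 ± 0.34 for JLP1, and 2.17 ± 0.34 for HO and 1.48 ± 0.27 for the arginine synthesis gene ARG1. Sulfate and methionine genes had a lower response in cho2 in 11 of 15 (14 adjusted over the list alone), with a median of -1.51 (camera adjusted p = 3.7e-39 with the preset correlation, adjusted p = 0.0973 with an estimated correlation). Of the 137 cytosolic ribosomal protein genes 0 passed limma at 3 h, with 13 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2 (0 adjusted over the list alone). Limma called 5 genes with a response higher in cho2, namely HO, IZH4, ARG1, PHO12 and ARG4, and 41 lower, and 566 had an unadjusted p under 0.05. With TMM scaling 16 were higher and 46 lower, so the higher share moved from 10.9% to 25.8%. With the preset correlation, camera called 9 lists up and 16 down, and with an estimated correlation 0 lists. The count of 46 was 30 without the second cho2 YPL library and 164 without the first cho2 library at 3 h.

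Calls were also compared between contrasts that share no library. They still share 1 spread per gene from the same fit, so genes with a small spread are called more easily in both. The counts for independent calls are therefore only a reference, and an excess over them can come in part from that shared spread. At 1 h and 3 h in SL, 54 genes were lower in cho2 in both comparisons, where independent calls would give 10.3, and 9 were higher in both, where independent calls would give 1.45; 9 were called in opposite directions (8.96 if independent). Of the genes called in YPL, 13 were called in the opposite direction at 1 h (1.41 if independent), MET3, MET5, MET10, MET14 and MET17 among them, while 5 were higher in both (0.800 if independent) and 3 lower in both (0.280). The genes called in the same direction between the strains in YPL, at 1 h and at 3 h were SPS100 and YGL262W, higher in cho2, and CHO2. Of these, YGL262W was chosen after its values were seen. For the change from YPL to 1 h, 1439 genes rose and 1348 fell in both strains (556 and 383 if independent), and 9 moved in opposite directions.

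**Figure D3:**
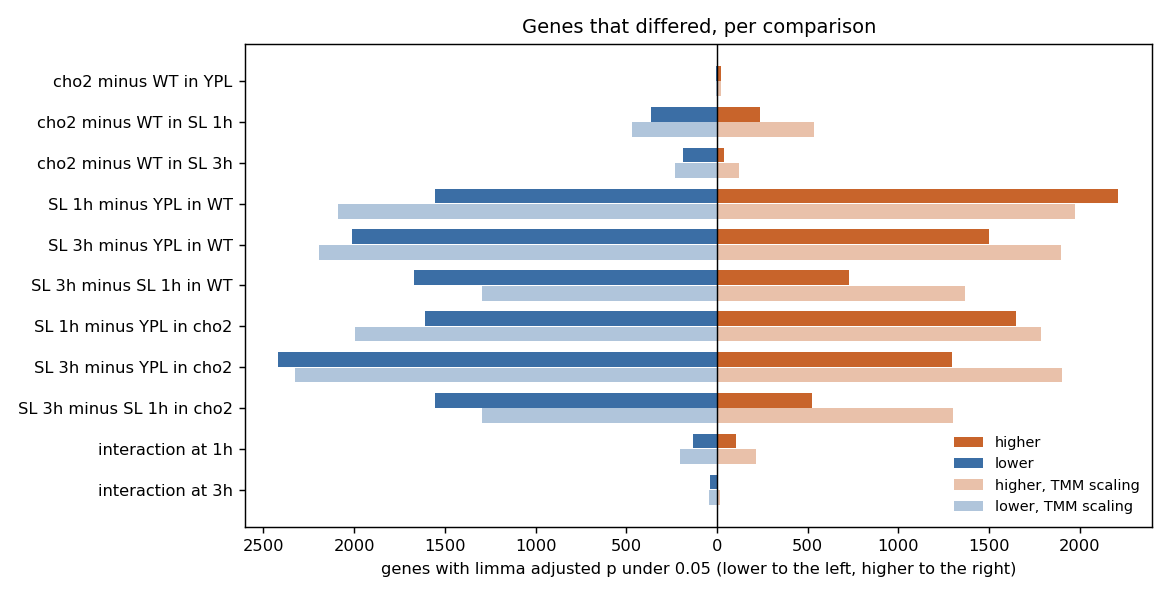
Number of genes (horizontal axis) past limma adjusted p under 0.05 in each of the 11 comparisons (vertical axis), higher to the right and lower to the left, with deposited scaling in full colour and TMM scaling in pale colour. In YPL 22 genes were higher and 5 lower in cho2, and at 1 h in SL 238 and 366.

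**Figure D4:**
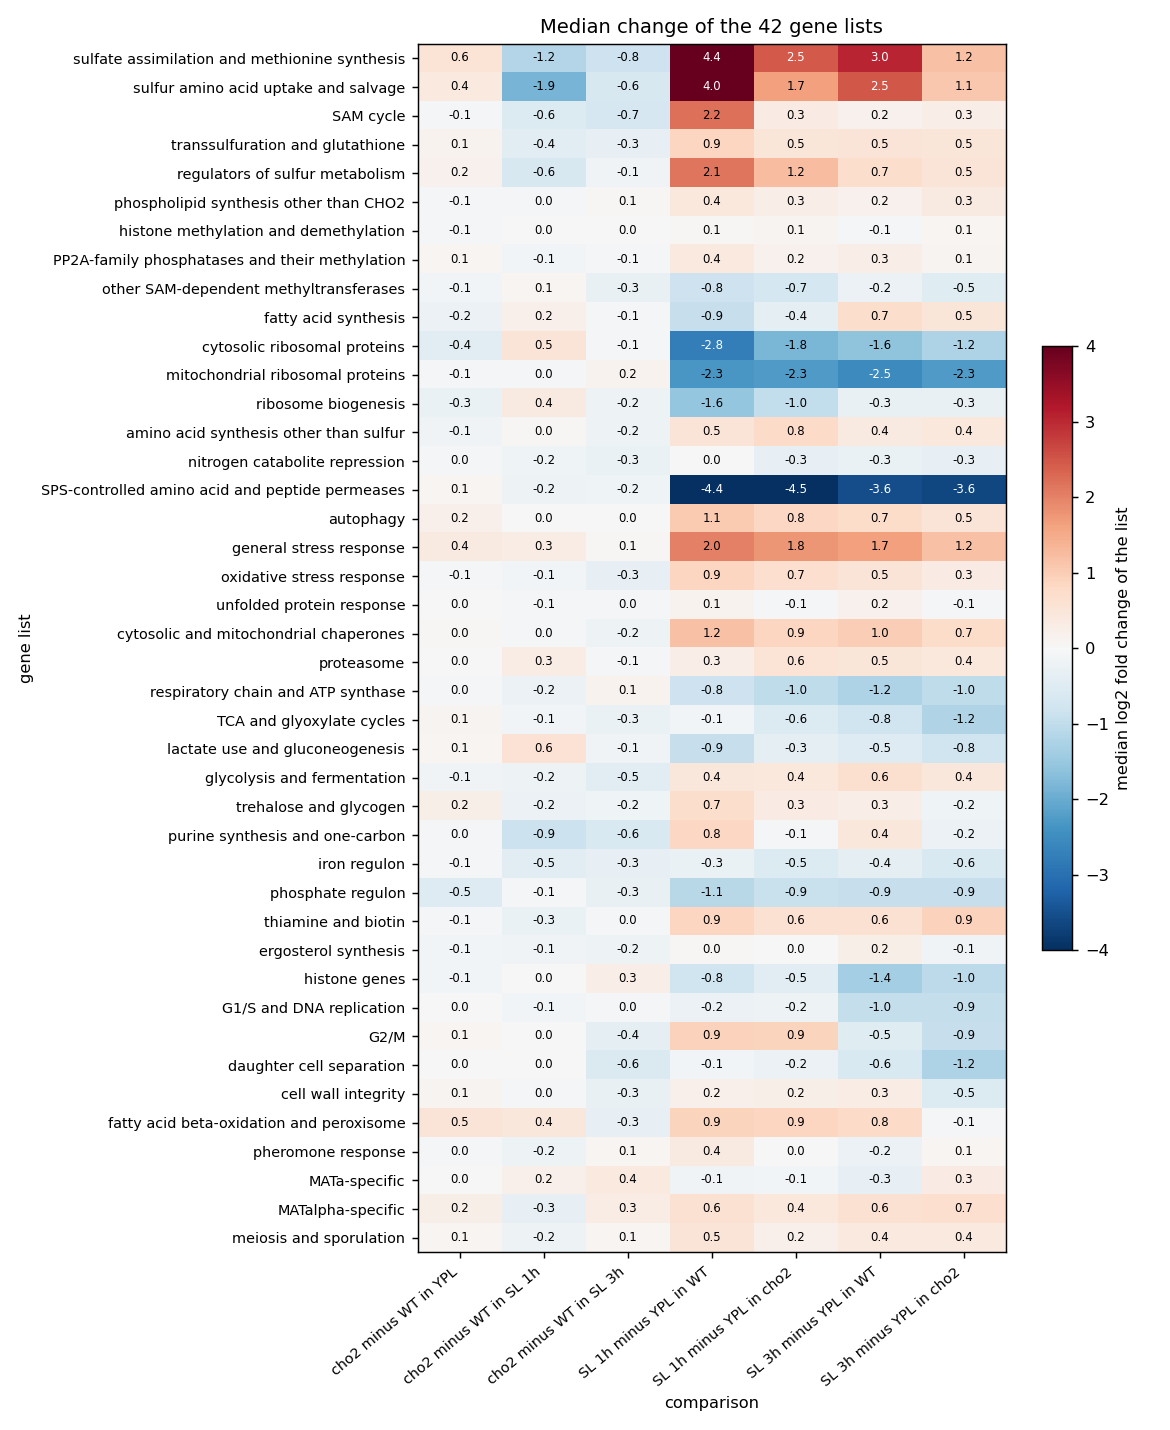
Median log2 ratio of the 42 gene lists (vertical axis) in 7 comparisons (horizontal axis), with colours limited to the range from -4 to 4. The sulfate and methionine list stood at 0.55 in cho2 minus WT in YPL and at -1.16 at 1 h in SL.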

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

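Tests of the scaling, of swapped labels, of a response ahead apart from the cell cycle, of the number of sulfate and methionine genes without copies, of the factor of a library and of shallow sequencing were chosen only after the results were seen; tests of near-identical copies of ribosomal protein genes, of mitotic entry genes and of abundant genes were set before. The results of the next 3 paragraphs are differences between the strains in the response to SL, tested as interactions with limma for genes and camera for lists.

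At 1 h several genes of sulfur uptake and assimilation had lower responses in cho2. The differences were -4.15 for MET3, -3.97 for MUP1, -3.33 for MET10, -3.29 for MET17 and -3.02 for MET5, and -3.41 for the one-carbon gene SHM2. MUP1 and SHM2 rose in WT (2.76 and 2.03) and fell in cho2 (-1.20 and -1.38). The response was higher in cho2 for the formate dehydrogenase genes FDH2 (2.96, overlapping another gene) and FDH1 (2.93), for DPA10 (2.85) and for INO1 (2.58) of inositol synthesis. It was also higher for the hexose transporter genes HXT6 (2.15) and HXT7 (2.09), near-identical copies. By 3 h FDH1 stood higher in both WT libraries (14440 and 11052) than in both cho2 libraries (10257 and 7789). DPA10 reached 16008 ± 4757 in WT at 3 h, from 1420 ± 129 at 1 h. At 3 h the sulfur genes MET3 (-3.94), MET17 (-3.18), JLP1 (-2.68), MET10 (-2.64) and MET14 (-2.48) and the deaminase gene CHA1 (-2.83) had lower responses, and HO (2.17), ARG1 (1.48), IZH4 (1.79), PHO12 (1.30, with a copy) and ARG4 (1.10) higher ones. The calls of IZH4, PHO12 and ARG4 ended under other settings. Each of these differences includes the strain difference in YPL, and both times share the same YPL libraries. In YPL, cho2 minus WT was 2.79 for MET3, 2.20 for MET17 and -1.31 for PHO12. At 3 h in SL it was -1.15 for MET3 and -0.97 for MET17.

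By list at 1 h, camera with the preset correlation called lower responses in cho2 for uptake and salvage (median -2.20), sulfate and methionine (-1.99), sulfur regulators (-0.91), purine and one-carbon synthesis (-0.80), trehalose and glycogen (-0.53), the SAM cycle (-0.43), the iron regulon (-0.41) and transsulfuration (-0.35). It called higher responses for cytosolic ribosomal proteins (0.91), ribosome biogenesis (0.59), lactate use (0.48), fatty acid synthesis (0.45), the phosphate regulon (0.44), the proteasome (0.33), amino acid synthesis (0.19) and other methyltransferases (0.11). With an estimated correlation 0 of these passed, with adjusted p = 0.0674 as the lowest.

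At 3 h the lower list responses were sulfate and methionine (-1.51), uptake (-1.21), beta-oxidation (-0.86), the SAM cycle and daughter cell separation (both -0.54), purine synthesis (-0.48), sulfur regulators (-0.44), mitotic entry (-0.43), cell wall (-0.43), trehalose (-0.40), transsulfuration (-0.38), the TCA cycle (-0.33), lactate use (-0.31), general stress (-0.29), oxidative stress (-0.26) and glycolysis (-0.25). Higher ones were histone genes (0.35), cytosolic ribosomal proteins (0.34), respiratory chain (0.21), mitochondrial ribosomal proteins (0.16), thiamine and biotin (0.14), fatty acid synthesis (0.13), phospholipid synthesis (0.09), ribosome biogenesis (0.08) and the phosphate regulon (0.04). With an estimated correlation 0 passed, with adjusted p = 0.0973 as the lowest. The median of all genes was -0.11, and the stress and glycolysis calls ended with TMM scaling (adjusted p = 0.0865 and 0.0539).

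Of 15 sulfate and methionine genes 6 were higher in cho2 in YPL and 14 lower at 1 h (list adjusted p = 0.313 and 0.187 with an estimated correlation), and 3 technical explanations were weighed. Scaling was argued against, since the list median nearest to 0 under TMM and quantile scaling was 0.48 in YPL and -1.09 at 1 h. Shared reads were argued against, since all 15 of the 15 members lack a near-identical copy, and a swap of labels, since CHO2 in the highest cho2 library was at 0.585% of the lowest WT library and CTR1 in the highest SL library at 0.783% of the lowest YPL library. Loss of a reaction that uses SAM remains an untested biological hypothesis, and whether cultures differed in growth stays open.

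In 54 of 137 cytosolic ribosomal protein genes the response at 1 h was higher in cho2, as a smaller fall (list adjusted p = 0.252 with an estimated correlation). The list median in cho2 minus WT was -0.41 in YPL and 0.51 at 1 h, so part of the difference lay in a lower level in YPL. Relative to the median of all genes, the list median at 1 h was 0.31 against the first WT library alone and 0.85 against the second. The 122 genes without a near-identical copy had a median interaction of 0.92, and the 15 with one 0.86. Reads shared with such copies cannot make the difference in those 122 genes. As they are most of the list, a median near that of the whole list was given beforehand, so this was hardly a test. Scaling was argued against by a median 0.97 above that of all genes under quantile normalization (1 factor per library, as in TMM, cannot change this difference). If all of cho2 were ahead in the time course, mitotic entry genes would be lower, but their median in cho2 minus WT at 1 h was 0.0290. Of the other 16 lists called from 1 h to 3 h in WT, with a different WT library at 1 h in each difference, 14 went the same way in cho2 minus WT at 1 h in 1 split of the WT libraries and 10 in both, among them ribosomal proteins, sulfate and methionine genes and lactate use. The amino acid permease list and the replication and cell cycle entry list went the other way in both splits. The latter is itself a cell cycle list, as only mitotic entry was set apart. Some of the 16 lists share genes, and they include the ribosomal and sulfur lists that showed the difference, so their count cannot decide. A response to SL that is ahead in cho2 apart from the cell cycle therefore stays open, as does a weaker response.

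The second cho2 library at 3 h read low, with its median gene at -0.33 log2, and its 11.9 M recovered reads argued against shallow sequencing. After 1 offset was removed its replicates differed by a median absolute deviation of 0.162, against up to 0.202 in other groups, which any uniform offset would give. The factor its values were divided by was 1.26 times the median-of-ratios factor recomputed here (0.886 to 1.04 in the others), which restates the offset. Per M recovered reads that factor was 0.124, against 0.104 to 0.111 in the others, a comparison also chosen after the values were seen. Scaling to the total instead moved the median gene of this library from -0.33 to -0.122 log2. Part of the offset thus went with the factor, which does not account for the -0.122 that stayed. Why the factor stood apart from the read total was not tested. For abundant genes the bound set in advance was met, with -0.0785 log2 left after the 10 most abundant genes were left out, but scaling to the total alone already left -0.122. Leaving those genes out removed only 0.0438, a comparison chosen after the values were seen. They held 10.2% of the reads, against 5.42% to 8.49% in the other libraries. These values argue against those 10 genes as the source of most of the -0.33. Whether a larger set of abundant genes played a part was not tested.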

How the results depend on the processing

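edgeR with TMM scaling, DESeq2 with its own size factors, and leaving out both 3 h libraries numbered 2 were settings chosen after the data were seen, not tests planned before. Main counts were 27 in YPL, 604 at 1 h and 225 at 3 h between strains, and 236 and 46 for the interactions at 1 h and 3 h; the cause of each change was not tested. With TMM scaling 1003, 353 and 418 genes passed for the strains at 1 h and 3 h and the interaction at 1 h. Quantile normalization gave 41 in YPL, 1044 at 1 h and 482 for the interaction at 1 h. Only the groups of a contrast gave 1392 at 1 h, 38 at 3 h (35 shared with the main calls) and 581 for the interaction at 1 h. With fewer libraries the count thus rose at 1 h and fell at 3 h. The main fit shares 1 spread per gene over all groups. Replicates correlated at r = 0.976 in both strains at 3 h, against 0.988 in WT and 0.996 in cho2 at 1 h. The p-values of the main fit may therefore be too small at 3 h. edgeR with TMM gave 1072 at 1 h and 452 for its interaction. DESeq2 gave 59 in YPL, 341 at 3 h and 108 for the interaction at 3 h with deposited scaling, and with own size factors 116, 1166 and 517 for the strains and 651 and 151 for the interactions. Without both 3 h libraries numbered 2 the counts were 46 in YPL, 1370 at 1 h and 582 for the interaction at 1 h.

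With each library left out, a lone sample was assumed to vary like the other groups. Counts ranged from 11 (without the second cho2 YPL library) to 37 in YPL, 192 to 1013 at 1 h and 130 to 1116 at 3 h, and 97 to 419 and 30 to 164 for the interactions. They ranged from 1355 to 3154 from 1 h to 3 h in WT and from 1221 to 2998 in cho2, while the other time contrasts stayed within 1.5 times. The camera direction of general stress, up for the strains at 3 h with a median of 0.05, turned to down, relative to the other genes, without the second cho2 library (median 0.13, adjusted p = 0.948; -0.0343 without the first) and without both libraries numbered 2 (0.0933, adjusted p = 0.564). For the interaction at 3 h the direction turned without the first cho2 library for general stress (-0.35, adjusted p = 0.8; range -0.42 to -0.18) and for glycolysis (-0.30, adjusted p = 0.848; range -0.525 to -0.0693).

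With the replicate block 36, 698 and 301 genes passed for the strains in YPL, at 1 h and at 3 h, and 315 and 64 for the interactions. The differences between replicates 1 and 2 correlated across genes between groups with r from -0.196 to 0.542 in 15 pairs of groups. The highest were WT in YPL with WT at 1 h (0.542) and WT with cho2 at 3 h (0.419). The main fit took no account of such shared deviations. Of 20273 alternative values for 845 gene results, 19610 kept their side of the threshold, 663 lost it and 0 changed direction. Of 4410 values for 210 list results, 3994 kept it and 412 lost it, 210 of these with an estimated correlation. Most of these results were named because they passed in the same data, and most settings reuse nearly all libraries. High retention was therefore likely beforehand and says little about other genes. DESeq2 with deposited scaling gave no adjusted p for 7 gene results. The depth of 3.17 M in the second WT library at 3 h limits low genes there.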

Other observations

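The test of copper was chosen only after the result was seen. Members of other lists also moved after the switch to SL, although with an estimated correlation 0 lists passed at 1 h (lowest adjusted p = 0.184 in WT and 0.145 in cho2). Of the vitamin genes for thiamine and biotin, 14 of 20 rose and 4 fell in WT at 1 h (15 and 4 adjusted over the list alone), with THI4 of thiamine synthesis at 3.88 ± 0.19 and BIO3 of biotin synthesis at 1.93 ± 0.20. Chaperone genes rose in 15 of 20 and fell in 4 (16 and 4 adjusted over the list alone), with SSA4, a heat-shock protein gene, at 3.12 ± 0.16. Phosphate regulon genes fell in 10 of 13 and rose in 2 (10 and 2 adjusted over the list alone). In cho2 at 1 h, genes under nitrogen catabolite repression fell in 11 of 23 and rose in 4 (11 and 4 adjusted over the list alone), with the proline breakdown gene PUT1 at -3.41 ± 0.17.

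At 1 h the copper uptake genes CTR1 (-7.08 in WT and -7.60 in cho2), CTR3 (-6.47 and -6.31) and the reductase genes FRE1 (-3.83 and -4.20) and FRE7 (-5.11 and -5.57) fell. The metallothionein genes CUP1-1 (4.06 and 5.36) and CUP1-2 (4.01 and 5.29), near-identical copies, and CRS5 (3.32 and 3.08) rose. FRE1, CRS5 and SOD1 were chosen after their values were seen, and SOD1 did not pass at 1 h in WT (limma adjusted p = 0.105, log2 -0.31) or in cho2 (adjusted p = 0.955, log2 -0.01). It was lower, against a response to copper, in WT at 1 h with TMM scaling (adjusted p = 0.0376, log2 -0.47) and in cho2 at 3 h with deposited scaling (adjusted p = 0.0496, log2 -0.38). The call in cho2 at 3 h ended with TMM scaling (limma adjusted p = 0.232, log2 -0.25), and in WT at 3 h SOD1 passed with neither scaling. Whether copper in SL caused this stays open: 14 of 16 changes passed in the direction such a response would give, but this restates the pattern, since the genes were picked for it and 2 are copies not read apart, and copper was not measured.

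The strains are given as MATa. The MATa genes MFA1 (237 to 916 over the 12 libraries) and STE2 (692 to 1549) were read, as were the MATalpha genes STE3 (93.0 to 339) and SAG1 (407 to 1023), while MF(ALPHA)1 lay between 3.03 and 34.9.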
